A study of Mus musculus with 6 samples.

How the data were processed

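RNA from purified C57BL/6 splenic NK cells kept for 36 h with or without 0.2 mM oleic acid (OA) was measured in 6 libraries, 3 control and 3 OA. Per the labels' protocols, RNA was taken up in TRIzol, extracted with a column kit and made into libraries with an RNA-seq kit for the MGI platform. Bowtie2, RSEM 1.3.1, DESeq2 1.4.5 and the mouse build mm10 are named per the submitters' processing notes, without roles or order; the annotation and any filter were not given in the sources used here. The one table used lists 559 genes. Per the file headers, it holds TPM (a transcript's share of its library on a common scale) for each library and a mean TPM per group, made by the authors. Per the file headers, it also holds the authors' log2 fold change of OA over control and the authors' P value and Q value for each gene. The largest Q value was 0.0499, and the ratio of Q to P at the largest P, times the rank, came to 18009, the number of tests a Benjamini-Hochberg adjustment would have covered. Genes outside the table were not analysed here. The authors' log2 fold change differed from the log2 ratio of the mean TPM by a median of 0.00645, and its sign differed from that of limma for 0 genes.

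TPM values are scaled within each library and keep no read numbers, so the depth and the counting error are unknown and no count test was run. A TPM is a share of all transcripts, so a change in abundant transcripts or in the mixture of cells shifts the TPM of other genes. Restricting the table to genes that passed a test on these libraries makes group differences in it larger than in unselected genes. The libraries were compared in pairs before averaging; no pair of libraries was identical over the table, with exactly equal TPM for at most 14 of the 559 genes, and the median absolute log2 difference was 0.0456 between control replicates 1 and 2, 0.125 and 0.139 between control replicate 3 and the other controls, 0.0714 between OA replicates 1 and 2, and 0.201 and 0.143 between OA replicate 3 and OA replicates 1 and 2.

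Samples were grouped by the treatment in their labels, and columns were matched to samples by the sample titles. The design fixed before the data were examined allowed for counts, normalized values or a comparison table; as the table held TPM, limma 3.58.1 in R 4.3.3 was run on log2(TPM + 1) for all 559 genes, with no filter, no covariate and Benjamini-Hochberg adjusted p under 0.05, two-sided. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Values are given as mean ± SD of TPM over 3 libraries. On simulated data with the spread of these 559 genes and 200 changed genes, in 20 simulations, limma called 38.5% of genes with a true log2 change of 0.25, 76.4% at 0.5, 90.1% at 1 and 93.1% at 2, and 2.8% of calls were false. The simulated genes varied independently and were not selected on the group difference. These shares therefore do not carry over to the calls on the listed genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, tests and plots.

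Before the data were examined, 31 gene lists with 874 distinct symbols were fixed, of which 171 symbols were listed. For the 18 lists with at least 5 listed members, the numbers of members higher and lower in OA were compared with the rest of the table by a two-sided Fisher's exact test, adjusted over the 18 lists. Genes are not independent, so these p-values are too small where members move together. In 100 simulations, 0 of 1800 random lists and 100 of 100 lists of 12 genes planted in one direction were called. Smaller planted lists were not tried, and a list of 5 higher members could not reach an adjusted p under 0.05 against this table. The named genes were fixed by rule before the data were examined. They were the 10 largest changes in each direction among genes with adjusted p under 0.05 and no overlap between the groups, leaving out unnamed models and genes whose higher group mean was under the median of 88.4 TPM. To these were added up to 4 members with the smallest adjusted p from each list with at least 3 listed members, and a set of genes named always, among them Cpt1a, Pdk4, Plin2, Angptl4, Scd1, Scd2, Ifng, Gzmb, Gzma, Prf1, Ncr1, Klrk1, Tbx21, Eomes, Myc and Mki67. Some genes that the rule names are not reported here. Etfb, Gdf15, Icos and Col3a1, the heart muscle genes and the gene families of the closing section were chosen after their values were seen. Coordinates are those of RefSeq on GRCm38, matched by gene identifier for 556 of the 559 genes.

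Alternatives tried were stricter thresholds, fold minimums, other pseudocounts, a level filter, libraries scaled to equal medians, the replicate number as a block, and leaving out each library in turn. Leaving out replicate 3 of both groups, a limma prior with an intensity trend and robust fit, and leaving out the heart muscle genes were added after the data were seen.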

Results

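Natural killer (NK) cells, lymphocytes that kill tumour and infected cells with granule proteins and secrete interferon gamma, were purified from the spleens of C57BL/6 mice. They were kept for 36 h with or without 0.2 mM oleic acid (OA), a monounsaturated fatty acid, and their RNA was sequenced in 3 control and 3 OA libraries. The question was how gene expression in NK cells differs after exposure to OA. The deposited table lists 559 genes, each with an authors' Q value under 0.05, and gives TPM, a transcript's share of its library on a common scale, in each library. A gene outside the table is called not listed here, which does not mean that it was unchanged. The listed genes summed to between 121857 and 126392 TPM per library, or 12.2% to 12.6% of the whole scale. TPM keeps no read numbers, so the depth of each library is unknown.

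Among the listed genes, transcripts of interferon gamma and the granzymes were lower after OA, and transcripts of the lipid storage and uptake genes Plin2, Hilpda and Cd36 were higher. Ifng, which encodes interferon gamma, fell from 1517 ± 235 to 879 ± 182 TPM (SD, n = 3 per group), and Gzma, Gzmb and Gzmc, which encode granzymes, fell to between 0.605 and 0.676 of the control level. Plin2, which encodes a coat protein of lipid droplets, rose from 493 ± 109 to 953 ± 126 TPM, and Cd36, which encodes a fatty acid uptake receptor, rose from 100.4 ± 22.9 to 219.9 ± 59.0 TPM. Arg1, which encodes arginase 1, rose from 60.8 ± 26.4 to 176 ± 23.2 TPM. Listed myeloid and B cell marker genes were mostly higher in the same OA libraries. Whether the lipid gene transcripts rose in NK cells or in other cells of the samples was not tested.

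In limma on log2(TPM + 1), 201 listed genes rose and 224 fell at a Benjamini-Hochberg adjusted p under 0.05, and 134 did not pass. The genes were selected on the same libraries by the authors, so these counts describe the listed genes and are not a count of changed genes in NK cells. In the authors' deposited table, 287 of the 559 genes were higher in OA and 272 were lower. Most differences were small: per the authors' deposited table, 383 genes had an absolute log2 fold change under 0.5, and of the 87 genes at 1 or more, 82 were higher and 5 were lower. Of those 82, 42 were heart muscle genes that stood high in OA replicate 3, and limma called 8 genes higher and 3 lower at the same minimum. The libraries of the groups did not overlap for 523 genes, or 93.6%, against 10% by chance, although this too follows selection. The number of calls varied with the library left out. In limma 0 genes were called without control replicate 1 (171 higher and 168 lower at an unadjusted p under 0.05) and 0 without OA replicate 2 (159 and 168 unadjusted). It called 87 higher and 13 lower without control replicate 2, and 119 and 30 without control replicate 3. Without OA replicate 3 it called 174 and 138, without OA replicate 1 177 and 187, and without replicate 3 of both groups 190 and 191. No gene changed sign, which for the 523 genes without overlap could not have happened by leaving out libraries. Scaling the libraries to equal medians gave 162 higher and 82 lower, so that 66.4% of calls were higher, against 47.3% with the values as deposited.

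**Figure D1:**
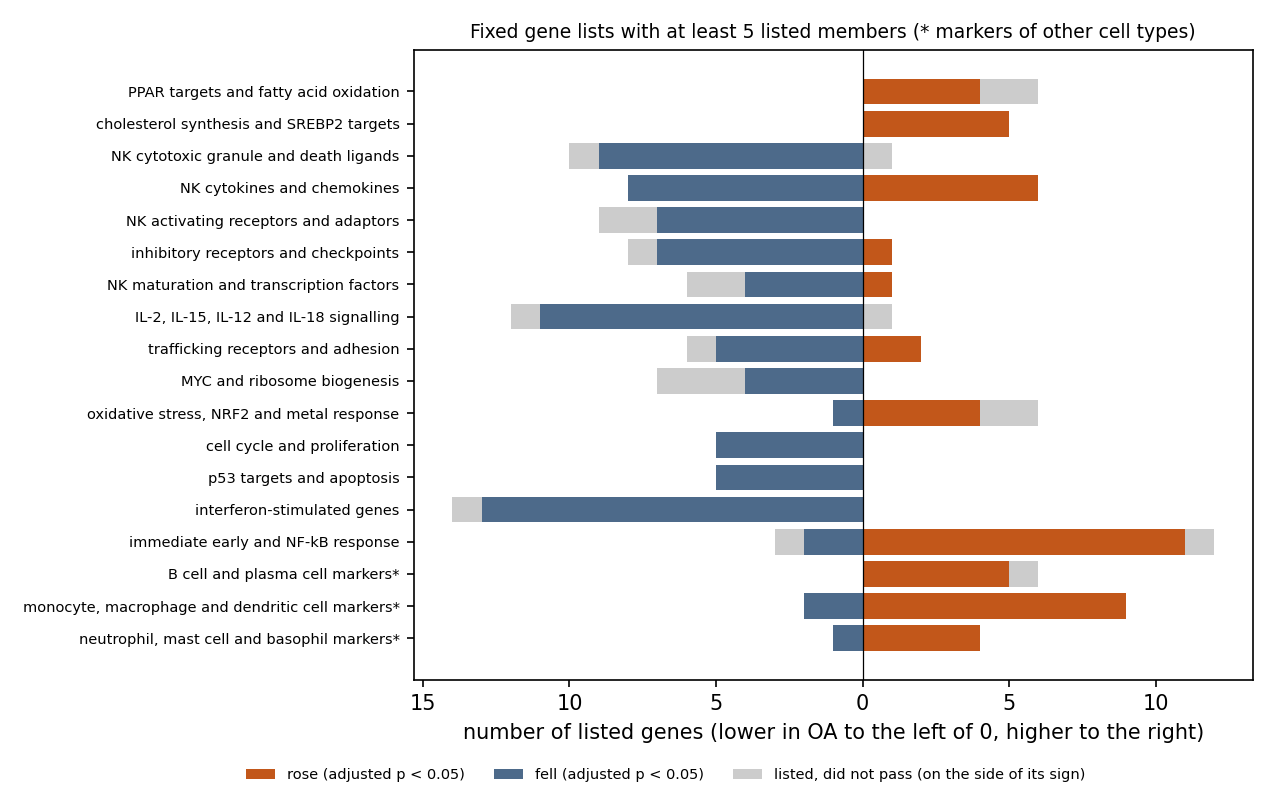
Numbers of listed genes of each fixed list (horizontal axis, genes) that rose or fell at an adjusted p under 0.05 in limma, with listed members that did not pass in grey on the side of their sign, for the 18 lists with at least 5 listed members. The interferon-stimulated list had 13 genes that fell and 0 that rose, and the immediate early and NF-kB list had 11 that rose and 2 that fell.

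Of the 25 genes fixed as NK cytotoxic granule proteins and death ligands, 11 were listed; 9 fell, 0 rose and 2 did not pass, and adjusted over the list alone 9 fell and 1 rose. Gzmc fell from 1204 ± 181 to 731 ± 130 TPM (log2 fold change −0.73, SE 0.175, adjusted p = 0.0279, limma), and Gzma from 861 ± 145 to 542.0 ± 84.8 TPM. Gzmb, the most abundant of the listed granzymes, fell from 1551 ± 207 to 1050 ± 144 TPM (log2 −0.56, SE 0.144, adjusted p = 0.0285, limma). Prf1, which encodes the pore-forming protein perforin, fell to 0.778 of the control level, and Nkg7, a granule membrane protein gene, from 579 ± 22.4 to 448 ± 47.8 TPM. The death ligand gene Tnfsf10 (TRAIL) fell to 0.708 of the control level. Counted by sign, 10 members were lower and 1 was higher, against 262 lower and 286 higher in the rest of the table (adjusted p = 0.0218, two-sided Fisher's exact test over 18 lists). Without control replicate 2 limma called 0 members and without control replicate 3 it called 1, and with members under the median level left out the direction did not pass (adjusted p = 0.0565, Fisher's exact test).

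The NK cytokine and chemokine list divided. Of 14 listed members, 8 fell and 6 rose, which did not part from the rest of the table (adjusted p = 0.595, Fisher's exact test). Without control replicate 2, 2 fell and 4 rose, and without control replicate 3, 2 fell and 3 rose. Beside Ifng (log2 −0.80, SE 0.195, adjusted p = 0.0281, limma), Lta (lymphotoxin alpha) fell from 359 ± 18.5 to 229 ± 38.8 TPM, Xcl1 from 528 ± 44.3 to 366 ± 34.5 TPM and Il13 from 244 ± 33.4 to 166 ± 18.2 TPM. Cxcl10, a chemokine induced by interferon gamma, fell to 0.668 of the control level. The chemokine genes Ccl4 and Ccl9, which myeloid cells also express, rose 1.47-fold and 1.96-fold.

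Listed activating receptor genes were lower. Of the 33 genes fixed as activating receptors and adaptors, 9 were listed, of which 7 fell, 0 rose and 2 did not pass. By sign 9 of 9 were lower (adjusted p = 0.00856, Fisher's exact test, and 0.0565 with members under the median level left out). Ncr1, which encodes the NK receptor NKp46, fell from 131 ± 7.42 to 91.8 ± 12.9 TPM (log2 −0.52, SE 0.116, adjusted p = 0.026, limma), and Klrk1, which encodes NKG2D, fell from 155 ± 4.94 to 118 ± 16.6 TPM. Klrb1f and the kinase gene Zap70 fell to 0.682 and 0.832 of the control level. Of the 30 genes fixed as inhibitory receptors and checkpoints, 9 were listed, of which 7 fell, 1 rose and 1 did not pass (adjusted p = 0.0532, Fisher's exact test). Among them Klrd1 (CD94) fell from 131 ± 7.72 to 98.5 ± 8.98 TPM and Lair1, Pvrig and Cd96 fell to 0.730, 0.766 and 0.806 of the control level. Adjusted over the list alone, 7 members of each receptor list fell. Without control replicate 2, and without control replicate 3, limma called 0 members of either list. The median log2 fold changes without control replicate 3 were −0.37 (activating) and −0.34 (inhibitory), against −0.39 and −0.40 with all libraries.

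**Figure D2:**
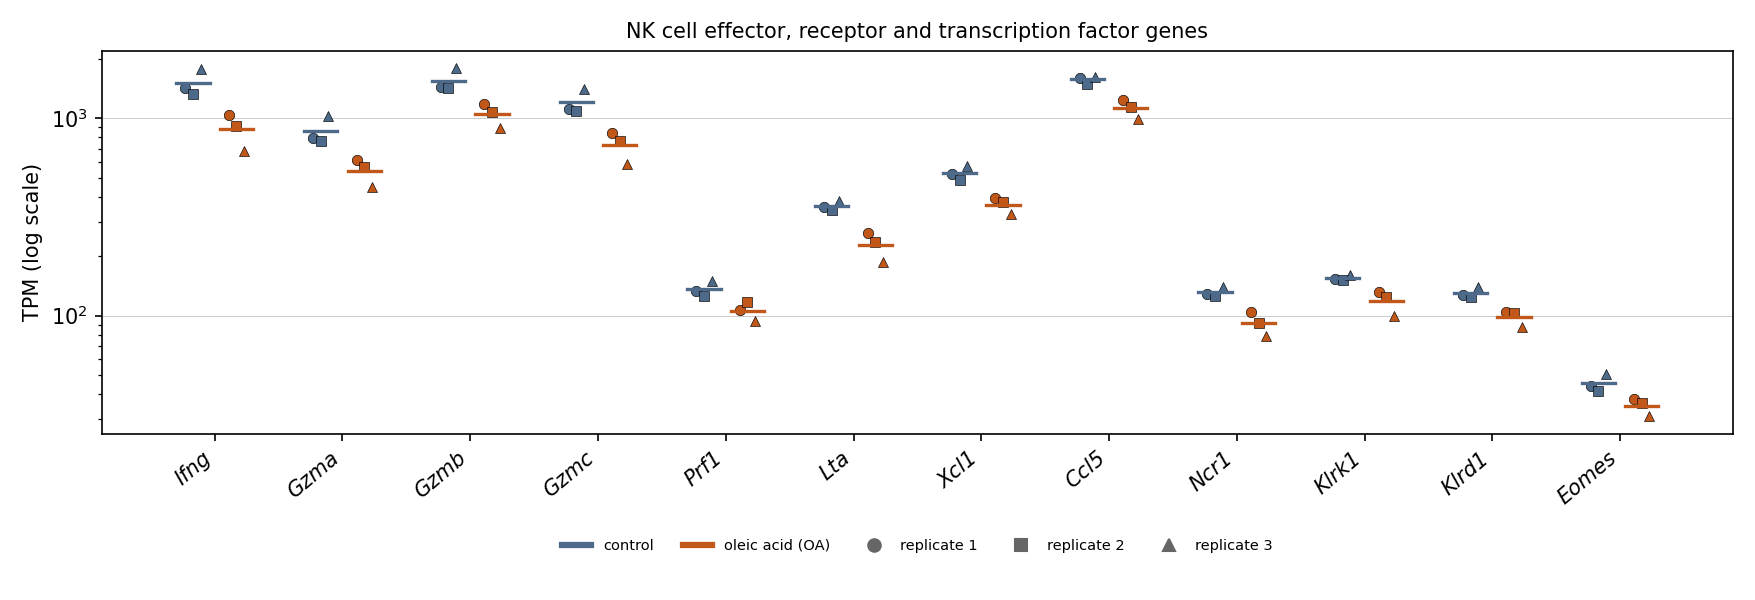
TPM (vertical axis, log scale) of NK cell effector, receptor and transcription factor genes in each library, with control in blue and OA in orange, marker shapes for replicates and a bar at each group mean. For each gene shown the 3 OA libraries lie below the 3 control libraries; Ifng means are 1517 TPM in control and 879 TPM in OA.

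The list of IL-2, IL-15, IL-12 and IL-18 signalling genes, cytokine pathways that sustain and activate NK cells, had 13 listed members; 11 fell, 0 rose and 2 did not pass, and the counts were the same adjusted over the list alone. By sign, 12 were lower and 1 was higher (adjusted p = 0.00856, Fisher's exact test). In limma 0 members were called without control replicate 2 and 0 without control replicate 3. The median log2 fold change of the list was −0.28 without control replicate 3, against −0.32 with all libraries. Il2ra, the alpha chain of the IL-2 receptor, fell from 309.6 ± 8.5 to 223.6 ± 31.7 TPM, Il12rb1 from 185 ± 12.9 to 145 ± 10.3 TPM and Pim2 from 291 ± 21.8 to 208 ± 28.7 TPM. Socs1 and Cish, on the same list, fell to 0.835 and 0.879 of the control level. The list does not separate activators from inhibitors of these pathways, so its counts do not measure pathway activity. Of 7 listed NK maturation genes and transcription factors, 4 fell, 1 rose and 2 did not pass (adjusted p = 0.0821, Fisher's exact test), and 0 were called without control replicate 2, control replicate 3 or OA replicate 3; Eomes, a T-box factor of NK cells, fell from 45.6 ± 4.77 to 34.9 ± 3.58 TPM and Id2 to 0.880 of the control level. Tbx21 was not listed. Of 8 listed trafficking and adhesion genes, 5 fell and 2 rose (adjusted p = 0.187, Fisher's exact test; 0 fell and 1 rose without control replicate 2, and likewise without control replicate 3), with Cxcr6 and Icam1 lower and the chemokine receptor gene Ccr1 1.29-fold higher.

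Interferon-stimulated genes gave the smallest p of the lists. Of 14 listed members, 13 fell, 0 rose and 1 did not pass; adjusted over the list alone 14 fell, and 14 of 14 were lower by sign (adjusted p = 0.00063, Fisher's exact test). Irf1, a transcription factor induced by interferon gamma, fell from 467 ± 28.1 to 382 ± 27.4 TPM (log2 −0.29, SE 0.079, adjusted p = 0.0305, limma), and Irgm1, Isg15 and Rtp4 fell to 0.821, 0.795 and 0.714 of the control level. Without OA replicate 3, 3 members fell; without control replicate 3, 2 did, and without control replicate 2, 0 did. Of 7 listed MYC and ribosome biogenesis genes, 4 fell and 3 did not pass, with 7 of 7 lower by sign (adjusted p = 0.0223, Fisher's exact test); Myc fell from 101.7 ± 5.65 to 87.0 ± 6.62 TPM, and adjusted over the list alone 0 members fell. With members under the median level left out, the direction of the MYC list did not pass (adjusted p = 0.0565, Fisher's exact test). Mxd1, on this list, fell to 0.853 of the control level, and the list does not separate activators from inhibitors of MYC. All 5 listed cell cycle genes fell, among them Rrm2, Cdc6, Ccnd3 and Rrm1, as did all 5 listed p53 target and apoptosis genes, among them Gadd45g, Casp4, Bcl2 and Bak1 (adjusted p = 0.0552 for each list, Fisher's exact test). Without control replicate 2, and without control replicate 3, limma called 0 members of the MYC, cell cycle and p53 lists. Mki67 was not listed.

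Listed lipid genes were mostly higher. The cells that carried these transcripts were not identified. Only the PPAR and cholesterol lists had the 5 listed members needed for a test of direction, and 100% of those members were higher. Neither list passed against the whole rest of the table. For 5 higher members this outcome was fixed by the list size (unadjusted p = 0.0618 with 5 of 5 higher, Fisher's exact test). Both listed members of the lipid droplet list rose: Plin2 by 0.97 on the log2 scale (SE 0.200, adjusted p = 0.026, limma) and Hilpda, which encodes an inhibitor of lipid droplet lipolysis, from 144 ± 37.6 to 297 ± 26.8 TPM. Of 6 listed PPAR targets and fatty acid oxidation genes, 4 rose and 2 did not pass (adjusted p = 0.0552, Fisher's exact test; 0.0357 with the heart muscle genes described below left out of the rest of the table), and adjusted over the list alone 5 rose. Cpt1a, the gate enzyme of mitochondrial fatty acid entry, rose from 71.3 ± 5.02 to 92.5 ± 4.97 TPM (log2 0.37, SE 0.076, adjusted p = 0.026, limma). The carnitine carrier gene Slc25a20 rose 1.29-fold, and Acot1 rose from 1.01 ± 0.416 to 2.99 ± 1.14 TPM. Pdk4 did not pass (adjusted p = 0.144, limma): it stood at 0.35, 0.34 and 0.28 TPM in the control libraries and at 0.64, 1.51 and 18.83 TPM in OA replicates 1, 2 and 3. Etfb, named after its value was seen, did not pass either (adjusted p = 0.0508, limma). Without OA replicate 3 all 6 members rose; without control replicate 3, 2 did, and without control replicate 2, 0 did. Angptl4 was not listed.

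All 5 listed cholesterol synthesis and SREBP2 target genes rose by small amounts (adjusted p = 0.0821, Fisher's exact test, and 0.0468 without heart muscle genes in the rest of the table); 5 also rose adjusted over the list alone, 2 without control replicate 3 and 0 without control replicate 2. Among them Hmgcs1 rose 1.21-fold, Msmo1 1.20-fold and Fdps 1.18-fold. Scd1, the desaturase that makes oleic acid from stearic acid, was the 1 listed member of the fatty acid synthesis list and rose from 12.9 ± 1.88 to 20.6 ± 1.09 TPM; Scd2 was not listed. Of 3 listed LXR targets, the sterol exporter gene Abca1 rose from 21.7 ± 1.23 to 29.0 ± 1.13 TPM, Apoe rose 1.29-fold and Arl4c fell to 0.856 of the control level. Apoe is also on the monocyte, macrophage and dendritic cell list. Of 4 listed glycolysis genes, Vegfa rose 1.31-fold and Hk2 fell to 0.847 of the control level, while Tpi1 and Ldha did not pass. No gene of the oxidative phosphorylation list or of the mitochondrially encoded list was listed.

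**Figure D3:**
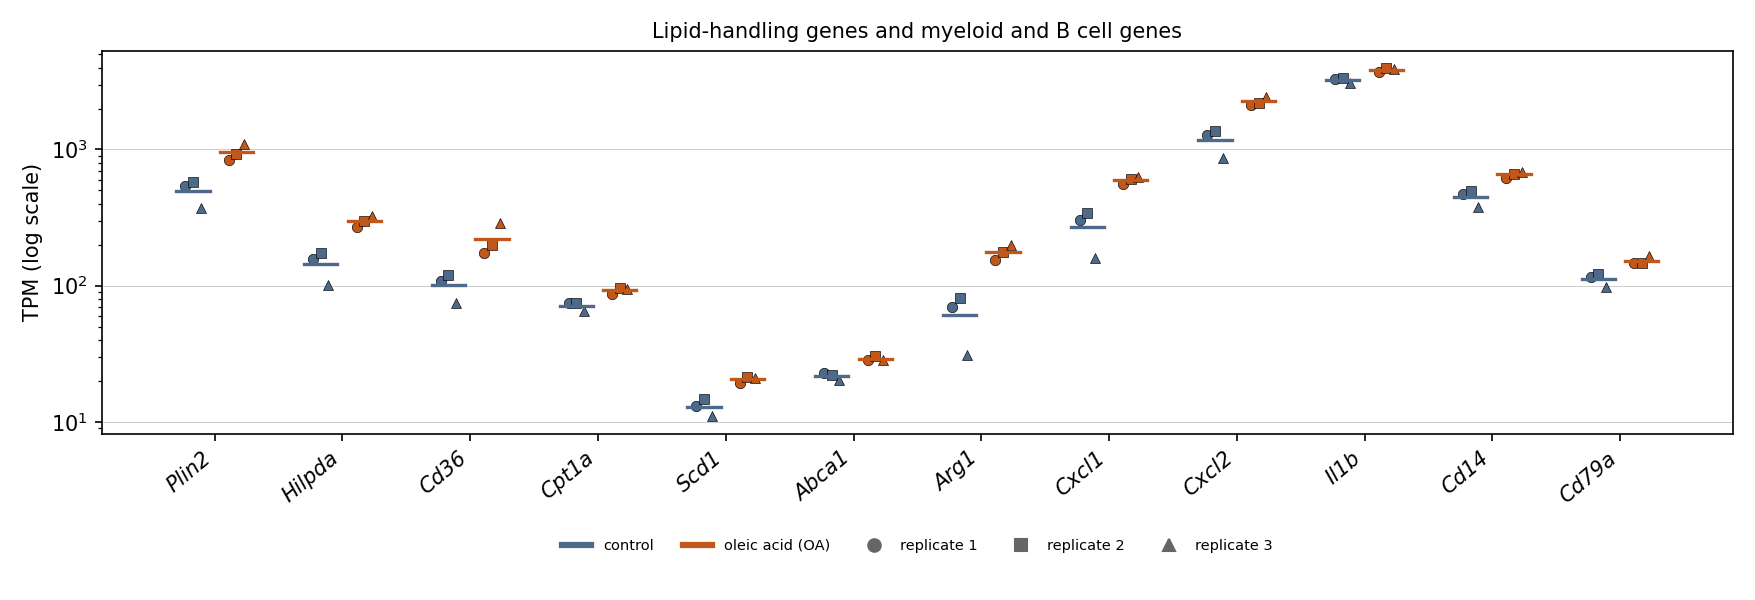
TPM (vertical axis, log scale) of lipid-handling genes and of myeloid and B cell genes in each library, with control in blue and OA in orange, marker shapes for replicates and a bar at each group mean. For each gene shown the 3 OA libraries lie above the 3 control libraries; Plin2 means are 493 TPM in control and 953 TPM in OA.

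Of 15 listed immediate early and NF-kB genes, 11 rose, 2 fell and 2 did not pass, and 12 rose adjusted over the list alone (adjusted p = 0.0552, Fisher's exact test; 0.0357 without heart muscle genes in the rest of the table). Without control replicate 2, 6 rose. Fos rose from 62.5 ± 3.13 to 90.4 ± 12.6 TPM, and Nr4a1, Dusp6 and Dusp1 rose 1.34-fold, 1.27-fold and 1.26-fold. Of 7 listed oxidative stress, NRF2 and metal response genes, 4 rose, 1 fell and 2 did not pass (adjusted p = 0.148, Fisher's exact test); 1 rose without control replicate 2 and 1 without OA replicate 1, and 2 rose without control replicate 3 and 2 without OA replicate 3. Ptgs2, which encodes cyclooxygenase 2, rose from 721 ± 21.2 to 928 ± 66.7 TPM, and Slc7a11 and Gclm rose 1.15-fold and 1.21-fold, while the transferrin receptor gene Tfrc fell to 0.881 of the control level. Both listed members of the integrated stress response list, Slc7a11 and Gdf15, rose. The 2 listed genes of the unfolded protein response and the 1 listed heat shock gene did not pass.

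Markers of other cell types were present in all 6 libraries and differed between the groups. The interleukin gene Il1b, which myeloid cells express strongly, stood at 3246 ± 137 TPM in control and 3850 ± 111 TPM in OA, above the level of Ifng in both groups. Of 11 listed monocyte, macrophage and dendritic cell markers, 9 rose and 2 fell (adjusted p = 0.0821, Fisher's exact test); 3 rose and 0 fell without control replicate 2, and 6 rose without control replicate 3 and 6 without OA replicate 3. Cd14 rose from 447 ± 61.2 to 655 ± 35.8 TPM, and Mmp12 rose 1.29-fold, while Ly6c2 fell from 139 ± 4.12 to 91.3 ± 15.3 TPM. Of 6 listed B cell and plasma cell markers, 5 rose and 1 did not pass (adjusted p = 0.0552, Fisher's exact test, and 0.0357 without heart muscle genes in the rest of the table), and 3 rose without control replicate 2; Cd79a rose from 112 ± 12.3 to 153 ± 9.88 TPM, and Ly6d, Mzb1 and Spib rose 1.61-fold, 1.46-fold and 1.47-fold. Of 5 listed neutrophil, mast cell and basophil markers, 4 rose and the basophil protease gene Mcpt8 fell (adjusted p = 0.396, Fisher's exact test), with 3 that rose and 0 that fell without control replicate 2; Mmp9 rose from 2.85 ± 0.739 to 6.52 ± 0.104 TPM and Il6 1.26-fold. Both listed T cell markers, Icos and Cd28, fell, as did both listed innate lymphoid markers, Cxcr6 and Tnfsf10. Of 2 listed erythroid and megakaryocyte markers 1 rose, and the 1 listed stromal marker, Col3a1, did not pass.

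By the fixed rule, the largest rises were in Arg1, a member of the monocyte, macrophage and dendritic cell list (log2 1.62, SE 0.383, adjusted p = 0.0274, limma), the neutrophil-attracting chemokine genes Cxcl1 (2.34-fold), Cxcl3 (2.23-fold) and Cxcl2 (1.96-fold), the glutamine synthetase gene Glul (1.73-fold) and Serpinb2 (1.73-fold), together with Cd36, Hilpda, Ccl9 and Plin2. The largest falls were in Nos2, which encodes inducible nitric oxide synthase and fell from 113 ± 23.6 to 61.1 ± 13.4 TPM, in the effector genes above, and in Ly6c2, of the same monocyte list, and Ly6i. On GRCm38, Ifng lies on chromosome 10 from 118441046 to 118445894, Gzmb on chromosome 14 from 56258836 to 56262334, Plin2 on chromosome 4 from 86626910 to 86670217 and Arg1 on chromosome 10 from 24915207 to 24927470. The TPM values are sums over each whole gene. Granzyme, Klr, Ly6 and Gbp genes have close copies, so reads may have been divided between them.

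Genes of heart muscle stood apart in single OA libraries. A heart muscle list of 66 genes, written after the values were seen, had 42 listed members, of which 42 were higher in OA by sign and 0 passed limma. Their TPM summed to 45.3, 72.0 and 55.7 in control replicates 1, 2 and 3, to 65.6 in OA replicate 1, to 593 in OA replicate 2 and to 8038 in OA replicate 3, or 0.804% of the whole scale. Of the fatty acid oxidation list, Cd36, Pdk4, Slc25a20, Etfb and Acot1 are also expressed in heart. Leaving out the heart muscle genes left 201 genes that rose and 224 that fell. These counts could not change, since 0 of the 42 heart genes had passed and limma was not run again.

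**Figure D4:**
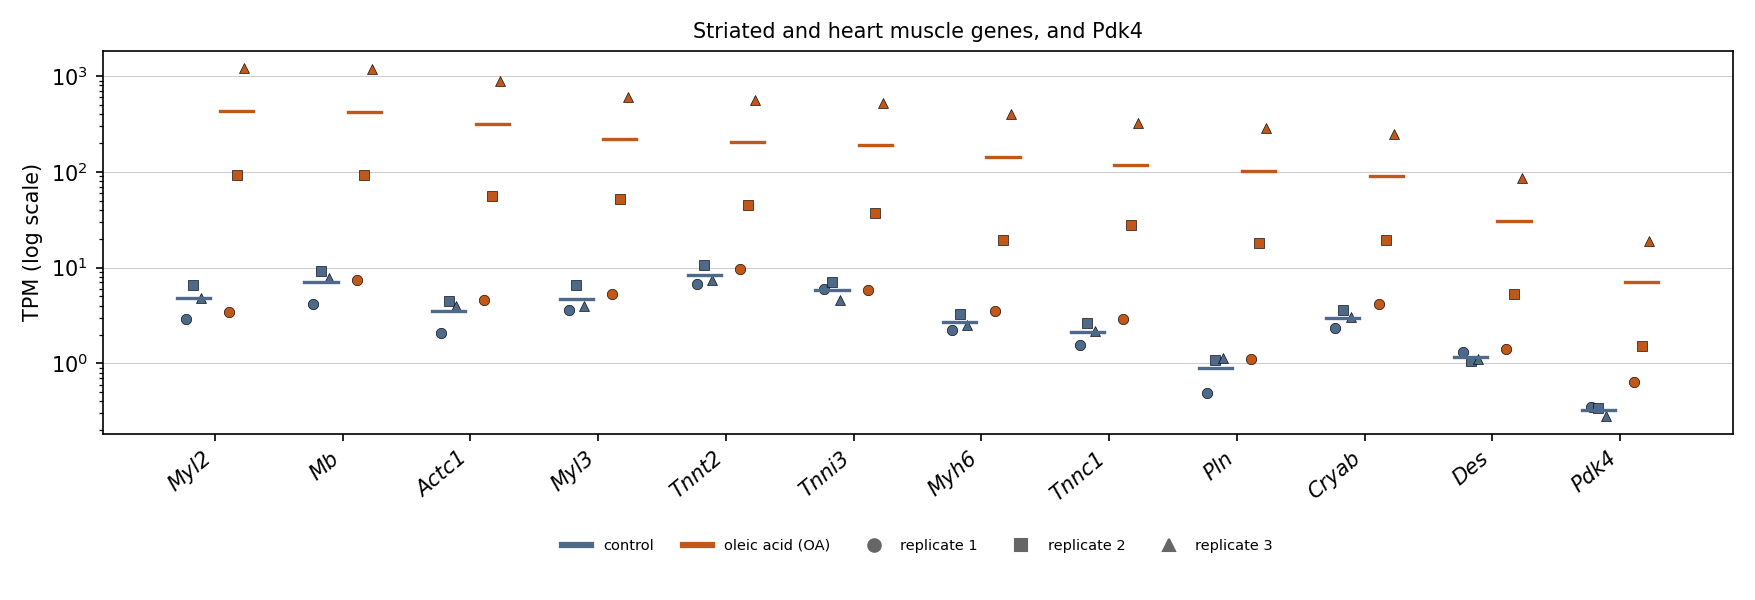
TPM (vertical axis, log scale) of 11 heart and striated muscle genes and of Pdk4 in each library, with control in blue and OA in orange, marker shapes for replicates and a bar at each group mean. OA replicate 3 lies highest for each gene and OA replicate 2 next, while OA replicate 1 lies near the control libraries; summed over the 42 listed heart genes the 3 OA libraries reach 65.6, 593 and 8038 TPM.

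Nothing in the labels says that the libraries came from separate animals or days, and the treatment is described as carried out once, so the p-values measure the spread between these samples, which may be technical. An exact permutation test of 3 against 3 libraries cannot go below 0.10, so the limma calls draw on the spread shared across the listed genes.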

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

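Leaving out replicate 3 of both groups, the intensity trend with robust prior, and both settings without heart muscle genes were chosen after seeing the data. No gene changed sign under any setting. For the 523 genes without overlap between the groups, neither a left-out library nor another pseudocount could change the sign. The counts of 201 genes higher and 224 lower stayed within 1.5 times with pseudocounts of 0.1 (205 and 224) and 5 (210 and 242), without unnamed models (197 and 218), without replicate 3 of both groups (190 and 191) and with the trend and robust prior (204 and 259). They moved to 0 and 1 at adjusted p under 0.01, 0 and 0 under 0.001 (213 and 252 at an unadjusted p under 0.05 in limma), 8 and 3 with an absolute log2 fold change of at least 1, 0 and 0 with at least 2, 90 and 125 with the level filter, and 162 and 82 with equal medians. In the stricter settings and the level filter, fewer genes could pass by construction; for equal medians the cause was not tested. Leaving out single libraries gave between 0 and 177 genes higher and between 0 and 187 lower; the 0 values came without control replicate 1 and without OA replicate 2, and the cause was not tested. With the replicate number as a block, limma called 0 higher and 0 lower (149 and 89 at an unadjusted p under 0.05). Same-numbered libraries correlated at 0.33, −0.11 and −0.08 in their deviations from the group means, and differently numbered ones at −0.40 to 0.35. This cannot decide whether the numbers pair the samples. The deviations of 3 libraries sum to 0, and the heart muscle genes were included. Of the 97 named genes, 94 lost their call under the block, without control replicate 1 and without OA replicate 2, 69 without control replicate 2, 58 without control replicate 3, 16 without OA replicate 3 and 9 without OA replicate 1. For the lists, 5 were mainly lower and 0 mainly higher at the main setting and under the block, each left-out library and the background without unnamed models, which follows from the signs alone. With the level filter 2 were mainly lower, and the granule, activating receptor and MYC lists lost their call. Without heart muscle genes in the background, 4 were mainly higher: the PPAR, cholesterol, immediate early and B cell lists. Requiring members to have an absolute log2 fold change of at least 1 or an adjusted p under 0.01 left no list with 5 members and gave no value. DESeq2 size factors and the low-count filter were not run, since they need counts. As depth is unknown, no limit from read numbers can be given.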

Other observations

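The tests of this part and their bounds were all chosen after the values were seen, and the rule for the markers of other cell types was made stricter after its p was known. Gene families were grouped by symbol; many of their members are in the fixed lists as well, so that these tests partly count the same genes again. All 7 listed killer cell lectin-like receptor genes fell (Klrc1, Klrc3, Klrd1, Klre1, Klri2, Klrb1f and Klrk1; median log2 −0.41; adjusted p = 0.0186, Fisher's exact test over the families tested; 6 are in fixed lists), as did all 6 listed guanylate-binding protein genes (median log2 −0.39, adjusted p = 0.029; 5 in fixed lists). The 7 listed immunity-related GTPase genes were lower, with 6 that fell (adjusted p = 0.0186; 4 in fixed lists). All 5 listed matrix metalloproteinase genes rose (Mmp8, Mmp9, Mmp12, Mmp13 and Mmp27; adjusted p = 0.111, Fisher's exact test). A family of 5 higher members could not pass, since 5 of 5 gave an unadjusted p of 0.0618 (Fisher's exact test). Among lymphocyte cytokines below the level set for named genes, Il9 fell from 59.1 ± 12.1 to 20.6 ± 10.9 TPM and Il17f from 76.2 ± 16.4 to 41.2 ± 6.71 TPM (SD, n = 3). Of 8 listed CC chemokine genes 6 rose, among them Ccl2 and Ccl7, and 2 fell, Ccl5 and Ccl24 (adjusted p = 0.43). Of 6 listed CXC chemokine genes 4 rose and 2 fell, Cxcl9 and Cxcl10 (adjusted p = 0.725).

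Heart muscle transcripts were high in OA replicate 3 and, less so, in OA replicate 2. Induction by OA alike in the 3 OA libraries is argued against by a median log2 difference of 4.69 between OA replicates 3 and 1 over the 42 listed heart genes, against at most 0.065 between control libraries. A candidate source is RNA of heart muscle in both libraries, since 1 source keeps its genes in 1 ratio. For 92.9% of heart genes, the OA replicate 2 excess was a share of the OA replicate 3 excess within 2-fold of the median (5.79%). Of the 245 other higher genes, 7.35% lay in that window, but their own median share was 93.6%. The window was set around the heart genes' median, so it cannot show whether other genes keep a ratio. Genes that respond jointly could also keep 1 ratio, so the ratio alone does not identify the source. The most abundant genes, Myl2 and Mb, had OA means of 434 and 426 TPM. Pdk4, whose share was 6.41%, may belong to the same excess, although at low TPM it was also higher in OA replicate 1 than in every control library. How such RNA could enter a sample of purified splenic cells stays open, and a response to OA in part of the OA cultures was not tested.

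Listed NK cell transcripts were mostly lower in OA while listed myeloid and B cell genes were mostly higher. Dilution by the heart muscle RNA is argued against for the listed activating receptors. Their median log2 fold change was −0.28 without OA replicate 3, against −0.39 with it. A smaller share of NK cell RNA was set against a panel of 8 killer cell receptor genes, which was lower by a log2 difference of −0.45. These 8 genes were themselves listed because the authors' test found a group difference. Receptor genes without a difference could not enter, so the panel's fall cannot measure the NK share. Whether a smaller share is the whole cause cannot be told apart from a response of NK cells to OA. Of the 18 lower granule and cytokine list members, 3 (Ifng, Gzmc and Lta) were called below the panel in limma and 2 above it. These 18 had also been selected for a group difference and for being lower, and 265 of all 559 genes were called relative to the panel. By libraries 6 of the 18 lay below the panel, 5 above it and 7 overlapped (10% lie apart by chance), and the test run first, a mean of Ifng, Gzma, Gzmb and Prf1, was −0.15 relative to the panel, at 2.57 standard errors, with a 95% interval of −0.30 to 0.01. Both may contribute: whether other cell types rose alike was not decided by members found on 1 list alone (4 lists, permutation p = 0.906) or by all listed members (6 lists, p = 0.112), since the monocyte and neutrophil lists go both ways and the T cell and innate lymphoid lists, lower in OA, hold genes that NK cells may express.

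Among the listed genes, the OA contrast runs along the same genes as the spread within both groups. These genes were selected by the authors on that contrast, so whether unselected genes share this spread is unknown. Across 517 genes without the heart list, the difference of control replicate 3 from control replicate 1 correlated at −0.68 with that of OA replicate 1 from control replicate 2, which shares no library, and the 6 such pairs with control replicate 3 lay between −0.74 and −0.46. Within OA, the difference of replicate 2 from replicate 1 correlated at 0.76 to 0.78 with that of OA replicate 3 from the controls, and the difference of replicate 3 from replicate 1 at 0.46 to 0.54 with that of OA replicate 2. The difference of replicate 3 from replicate 2 correlated less, at 0.25 to 0.30, with that of OA replicate 1 from the controls. Genes are not independent replicates, and the pairs share libraries with each other. Variation between preparations along the same genes is therefore a candidate source of part of the contrast, while a response to OA that differs in size between the OA libraries was not tested; control replicate 3 differs away from the OA libraries, and the difference between control replicates 1 and 2 gave 0.25 to 0.28.

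Of the 10 splits of the 6 libraries into 3 and 3, the real split gave 425 genes and the highest of the others 0, so that 1 split reached the count. The listed genes had been selected by the authors on the real split, which fixes this outcome, and 10 splits cannot give a share under 0.1, so the splits say nothing about chance.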
